A study of Mus musculus with 6 samples.

How the data were processed

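Expression was measured in mouse embryonic stem cells on 6 arrays of 12488 probe sets each. The arrays fall into 3 lines by their labels: wild type, H1 triple-null line 1 and H1 triple-null line 2, with 2 arrays per line. The deposited values are array intensities on a linear scale, 1 value per probe set and array, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. In the deposited table the trimmed mean of every array, with 2% of the probe sets left out at each end, lay between 99.5 and 99.8, so the values had been scaled to a common level and that scaling was kept. Detection calls are not used here. The labels do not say whether arrays of a line came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

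Probe sets were named from the platform annotation given with the series, with older symbols updated through a table of current mouse genes (assembly GRCm38.p6), which matched 10817 of the 10833 probe sets listed with 1 gene. A further 396 probe sets are listed with several genes and are named here only by their identifier and the genes listed, and 1193 have no gene listed. The 66 control probe sets were left out of the tests. Background was read from 19 bacterial and yeast control probe sets, whose highest signal per array lay between 9.1 and 17.2. Where a probe set was at or below that level on all arrays of a line, only a bound is given. It is an at-least fold of the geometric mean of the brighter arrays over the geometric mean of each dim array's highest background control. For genes with several probe sets, the one with the highest mean over all arrays stands for the gene in the gene lists.

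Values were tested as log2(value + 2), where the pseudocount is the 10th percentile of all values. Fold changes are therefore on the log2(value + 2) scale, which understates the change of dim genes. Probe sets were tested if their mean over all arrays was at or above the 40th percentile of such means (20.9 intensity units). This left 7453 probe sets, of which 6725 are listed with 1 gene, 253 with several and 475 with none, and 5654 genes. One model with a mean per line was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the lines shared an estimate of the spread, with 3 residual and 3.17 prior degrees of freedom. Contrasts were the average of the null lines minus wild type, each null line minus wild type, and line 1 minus line 2. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. By permutation alone, 2 arrays against 4 cannot give a two-sided p below 0.0667, so every adjusted p rests on the model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

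Gene lists, comparisons, filters and alternatives were fixed before the data were examined, except where the text says otherwise. Of 27 lists, 23 had at least 5 genes tested. They were core histones; chromatin and DNA methylation factors; maternally and paternally expressed imprinted genes; germline and Rhox genes silenced by DNA methylation; pluripotency genes; markers of extraembryonic endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast and feeder fibroblasts; Hox genes; interferon response and MHC class I; p53 targets; S phase and mitosis genes; ribosomal protein genes; glycolysis and hypoxia response; oxidative phosphorylation; cholesterol synthesis; the unfolded protein response with amino acid starvation; heat shock; and immediate early genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 23 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move one way on balance. The targeted H1 genes, the other linker histones, Xist with the Y-linked genes, and genes of the two-cell stage had too few genes tested and are given as values.

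Genes are named by a fixed rule: the 10 largest rises and 10 largest falls among genes past the threshold in the null average with all 4 null arrays on one side of both wild-type arrays, filled up with the smallest p where fewer passed; 5 on each side between the null lines, filled up in the same way; all linker histones, Xist and Y-linked genes on the array; and up to 4 members of each list with the smallest p. Probe sets outside the rule are named only with their reason. The comparison of each null line with wild type uses the same wild-type arrays, so the number of shared calls, the correlation and the covariance of the lines' changes were set beside 100 simulations of unchanged lines against those arrays.

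The procedure was tested on simulated data with 7453 probe sets for the null average, of which 200 were changed, in 10 runs. It called 65.9% of the probe sets changed 2-fold and 92.1% of those changed 4-fold, and 3.92% of the calls were false. A list of 25 genes shifted by 0.3 on the log2 scale had an unadjusted camera p under 0.05 in 10 of 10 runs, as did 2.93% of unchanged lists. The simulated genes varied independently, so these shares do not cover lists of correlated genes or the adjusted threshold used for the lists. The precision is limited by the number of arrays. Alternatives were no pseudocount and a pseudocount of 8 (the 25th percentile), no filter and a filter at the 60th percentile, quantile normalization, median centring, the replicate number as a block, a spread that follows the signal (eBayes with trend), a 2-fold minimum, a single group of the 4 null arrays, the mean over all probe sets of a gene, and leaving out each array in turn. No column of the table was left unused.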

Results

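Gene expression was compared between wild-type mouse embryonic stem cells, pluripotent cells derived from the early embryo, and embryonic stem cells in which the genes of 3 linker histones had been inactivated. Linker histones bind the nucleosome where DNA enters and leaves it. The inactivated genes are those of H1c, H1d and H1e, now named H1f2, H1f3 and H1f4. The comparison asks which genes depend on the amount of linker histone. Wild-type cells and each of 2 triple-null lines were measured on 2 arrays. The median signal per array lay between 34.2 and 39.8 intensity units, and the highest background control between 9.1 and 17.2. Across probe sets, which are not independent replicates, the log2 signals of arrays of the same line correlated with r between 0.972 and 0.977, and those of different lines with r between 0.959 and 0.98. The SD of the log2 difference between arrays of the same line was 0.333 for wild type, 0.371 for line 1 and 0.347 for line 2. The log2 ratio of the 3' to the 5' probe set, a measure of RNA integrity, was -0.25 and -0.13 for Gapdh on the wild-type arrays and between -0.26 and -0.16 on the null arrays. For Actb it was 0.28 and 0.26 on the wild-type arrays and between 0.21 and 0.4 on the null arrays.

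Of the targeted genes, H1f2 fell from 69.1 ± 1.27 intensity units (SD, n = 2) in wild-type cells to 12.5 ± 1.51 (SD, n = 4) in the null cells, a log2 change of -2.3 ± 0.11 (SE, limma adjusted p = 0.00119). The fall was -2.42 in line 1 and -2.18 in line 2, and 2 of the 4 null arrays remained above background. The probe sets of H1f3 (95388_at) and H1f4 (94718_at) were at or below background on every array, with wild-type means of 1.2 and 0.9, and so check nothing about these genes. The other linker histones did not move alike. H1f5, another replication-dependent linker histone, was at background in wild-type cells (6.3 ± 0.849, SD, n = 2) and rose to 41.2 ± 6.47 (SD, n = 4) in the null cells, at least 3.25-fold (adjusted p = 0.00221). H1f10 measured 242 in wild-type and 412 in null cells (log2 change 0.65 ± 0.39, SE, adjusted p = 0.534), and H1f1 21.5 and 29.9 (0.44 ± 0.22, SE, adjusted p = 0.466). H1f6 and H1f8, linker histones of germ cells, were below the filter, with wild-type means of 12.8 and 15.4 and null means of 13.4 and 9.72.

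In the average of the null lines, Meg3, Eif2s3y and Rhox5 had the largest rises among named genes past the threshold with a wild-type array above background, and H1f2 and Igf2 the largest falls among named genes past the threshold. Meg3, a maternally expressed noncoding RNA of the imprinted Dlk1 region, rose from 14.8 ± 0.849 (SD, n = 2) to 181 ± 19.8 (SD, n = 4), 10.9-fold, with 1 of the 2 wild-type arrays above background. Rhox5, an X-linked homeobox gene, rose from 254 ± 57.8 to 1250 ± 50.5, 4.98-fold. Igf2, a paternally expressed fetal growth factor, fell from 1740 ± 34.8 to 567 ± 118, 3.1-fold lower. Fbxo15, an F-box gene of undifferentiated embryonic stem cells, rose 2.07-fold to 341 ± 31.1.

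In all, 31 of the 7453 probe sets tested passed adjusted p 0.05 with limma in the null average, 21 higher and 10 lower, and 946 (12.7%) had an unadjusted p under 0.05. All 31 had the 4 null arrays on one side of both wild-type arrays, and 18 of the higher and 5 of the lower changed at least 2-fold. Among all tested probe sets, 1714 (23%) had the 4 null arrays on one side, 818 higher and 896 lower, against 13.3% if the 6 arrays were exchangeable. The arrays of line 2 lay on one side of the other 4 for 21.3% of the probe sets, and those of line 1 for 13.5%. The log2 change of Meg3 was 3.44 ± 0.14 (SE, adjusted p = 0.00119), and its other probe set, 160173_at, rose by 1.5 (adjusted p = 0.0209). The change was 2.31 ± 0.15 for Rhox5 (adjusted p = 0.00512) and -1.63 ± 0.12 for Igf2 (adjusted p = 0.00788). Eif2s3y, a Y-linked subunit of a translation initiation factor, rose from 10.2 ± 1.77 (SD, n = 2), with 1 wild-type array above background, to 61.8 ± 14 (SD, n = 4), a log2 change of 2.36 ± 0.13 (SE, adjusted p = 0.00217).

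The other named genes that rose were Mt4, a metallothionein of squamous epithelium, at least 2.28-fold from background to 29.5 ± 8.32 (SD, n = 4, adjusted p = 0.0191); Cyct, the testis cytochrome c, by 1.53 ± 0.16 on the log2 scale (adjusted p = 0.0344); Sgip1, by 1.37 ± 0.17 (adjusted p = 0.0433); and Cela1, a serine protease, by 1.23 ± 0.15 (adjusted p = 0.0465). Fbxo15 rose by 1.05 ± 0.13 (adjusted p = 0.0465), and Zp3, a glycoprotein of the egg coat, by 0.94 ± 0.11, from 35 ± 3.04 to 69.5 ± 13 (adjusted p = 0.0433). Besides H1f2 and Igf2, 6 named genes fell, with log2 changes between -1 and -0.83. Emp1, an epithelial membrane protein, fell from 232 to 115 (adjusted p = 0.0344), and Igfbp3, which binds insulin-like growth factors, from 374 to 191 (adjusted p = 0.0433). Tapbp, a chaperone of MHC class I peptide loading, fell from 282 to 149 (adjusted p = 0.0465), and Adam9, a membrane metalloprotease, from 115 to 62.7 (adjusted p = 0.0484). Col4a2, a basement membrane collagen, fell from 349 to 194, and Wwtr1, a coactivator of the Hippo pathway, from 162 to 90.9 (adjusted p = 0.0433 for each). Other probe sets of Tapbp (-0.39 and -0.24), Igfbp3 (-0.63) and Wwtr1 (-0.49) did not pass (adjusted p = 0.229, 0.568, 0.132 and 0.49). A second probe set of Igf2 was at background on all arrays. Serpinb9 (-0.85, adjusted p = 0.0508) and Frmd6 (-0.79, adjusted p = 0.0543), next by p on that side, did not pass.

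**Figure D1:**
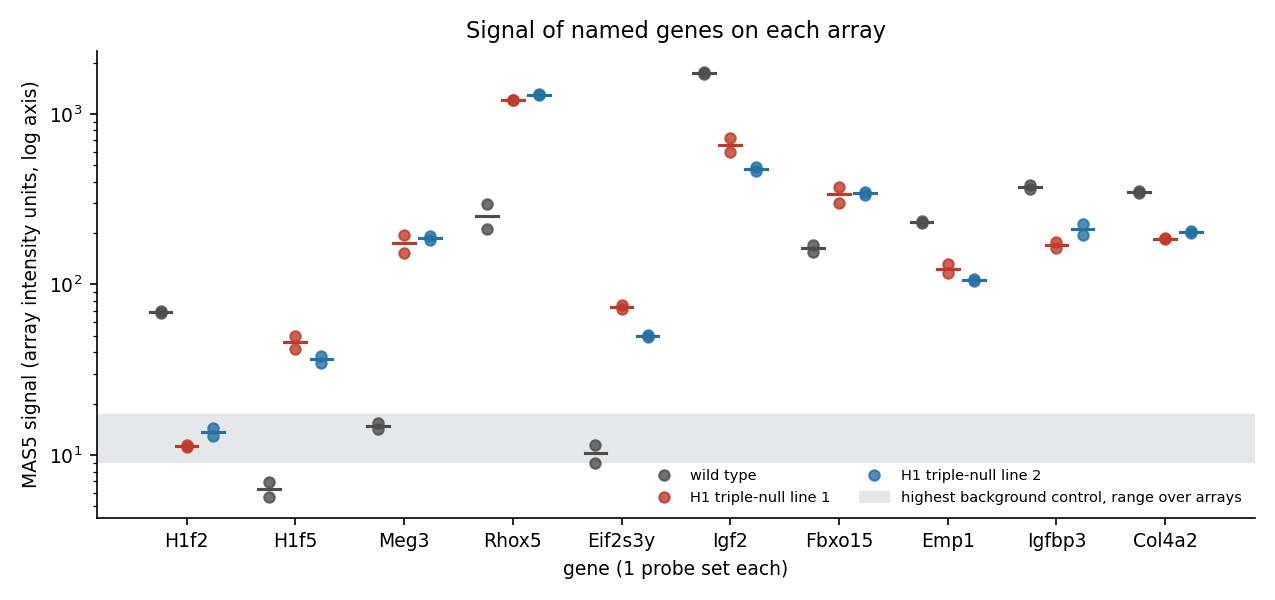
MAS5 signal (log axis, intensity units) of 10 named genes on each array; points are arrays, bars are means of a line, and the grey band spans the highest background control of the arrays. Wild-type signals of H1f5 lie below the band and those of Igf2, near 1740, lie above those of every null array.

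The other calls are second probe sets of Meg3 and Pfkp and probe sets that the annotation lists with several genes or with none, of which those below were chosen after their values were seen. Probe set 93028_at, which the annotation lists with both Mir675 and H19, rose from 115 ± 11.4 (SD, n = 2) to 853 ± 71.2 (SD, n = 4), a log2 change of 2.87 ± 0.13 (SE, adjusted p = 0.00119). Probe set 101883_s_at, listed with Xlr3a, Xlr3b and Xlr3c, X-linked lymphocyte-regulated genes, rose from background (adjusted p = 0.00788) to 18 in line 1 and 53.8 in line 2, at least 1.42-fold and 4.27-fold, and passed against wild type in line 2 (adjusted p = 0.00624) and not in line 1 (0.0772). Probe set 93833_s_at, listed with the histone genes H2bc4, H2bc6 and H2bc8, fell from 109 to 46.5 (log2 change -1.2, adjusted p = 0.0344). Of 5 probe sets listed with Sgip1 and Noct together, all higher in the null cells, 3 passed, at 1.03 (93909_f_at), 0.95 (98254_f_at) and 0.92 (97181_f_at). Probe sets 93907_f_at and 93908_f_at, at 0.82 and 0.87, did not pass (limma adjusted p = 0.0509 and 0.111). Pfkp, a glycolytic phosphofructokinase, rose by 1.28 with probe set 97834_g_at (adjusted p = 0.0344), and its brighter probe set 97833_at had a log2 change of 1.19 (adjusted p = 0.083). Of the unlisted probe sets, 95419_at rose from 222 to 783 (1.8, adjusted p = 0.00726).

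The number of calls depended on every array. It was 7 without either wild-type array, 13 and 8 without replicate 1 and 2 of line 1, and 12 without either replicate of line 2, against 31 with all arrays. It was 6 higher and 2 lower without the filter, and 48 higher and 53 lower with a spread that follows the signal. Meg3, H1f5, Eif2s3y, Rhox5 and H1f2 passed in every alternative that tested them, the 2-fold minimum and the single group of null arrays included. Apart from those 2 alternatives, Igf2 passed in 11 of 14, and each of the other 12 named genes in between 4 and 7.

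The list of germline and Rhox genes, which DNA methylation silences in somatic cells, lay higher in the null cells by camera at the preset correlation. Of 8 tested, 2 rose (Rhox5 and Zp3; 3 when adjusted over the list alone, with Tex19.1), none fell, and the median log2 change was 0.49 (camera adjusted p = 0.00152, or adjusted p = 0.196 with an estimated correlation). The call ends without the called genes (adjusted p = 0.18, a test chosen after the data were seen). Tex19.1, a germ cell gene, measured 108 in wild-type and 199 in null cells (0.83, adjusted p = 0.145), and Rhox6 16.2 and 30.7 (0.96, adjusted p = 0.386). The remaining members, Ddx4, Dazl, Dpep3 and Tnp1, had log2 changes of 0.15, 0.01, -0.09 and -0.18, and none of them passed. Imprinted genes went both ways. Of 15 maternally expressed genes tested, Meg3 alone rose (2 when adjusted over the list alone, with Phlda2 at 0.59, adjusted p = 0.12), and Osbpl5 and Gnas had log2 changes of -0.5 and -0.3 (adjusted p = 0.236 and 0.317). H19 is also on this list but was not among the 15. Probe set 93028_at, listed with both Mir675 and H19, stood outside the list test and rose by 2.87 (limma adjusted p = 0.00119). The list's median was -0.04, while its mean of 0.19 and the camera test pointed up (adjusted p = 0.895). Of 14 paternally expressed genes, Igf2 fell (1 higher and 2 lower when adjusted over the list alone), with Plagl1 at -1.28 (adjusted p = 0.121), Nnat at 0.54 (adjusted p = 0.219) and Peg10 at -0.48 (adjusted p = 0.306). The median was -0.1 (camera adjusted p = 0.314).

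Markers of extraembryonic endoderm and of mesoderm were lower in the null cells, and so were markers of fibroblasts, which serve as feeder cells in such cultures. Of 23 endoderm markers, Col4a2 fell (5 lower when adjusted over the list alone) and 19 had negative changes, with a median of -0.25 (camera adjusted p = 8.81e-05, or adjusted p = 0.196 with an estimated correlation). The keratins Krt8 and Krt18, abundant in simple epithelia, measured 1480 and 1670 in wild-type and 909 and 959 in null cells (-0.71 and -0.81, adjusted p = 0.0924 and 0.118), and Col4a1 measured 376 and 232 (-0.7, adjusted p = 0.134). Without keratins and type IV collagens, a part chosen after the data were seen, 18 genes had a median of -0.18 (camera unadjusted p = 0.0066). Gata4, Sox17, Sox7 and Apoe, chosen after their values were seen, were at -0.23, 0.05, 0.09 and 0.2. Of 16 mesoderm and primitive streak markers none passed alone, 14 had negative changes and the median was -0.26 (camera adjusted p = 0.00149, or adjusted p = 0.196 with an estimated correlation). Twist1, Wnt3 and Hand1 had log2 changes of -0.53, -0.39 and -0.39, and Flt1 one of -1.93 ± 0.49 (SE, adjusted p = 0.213). Of 24 fibroblast markers none passed over all probe sets (5 lower when adjusted over the list alone), 18 had negative changes and the median was -0.19 (camera adjusted p = 0.00111, or adjusted p = 0.196 with an estimated correlation). Among them, the contractile protein gene Acta2 measured 561 and 345 (-0.71, adjusted p = 0.121), Timp3 62.2 and 38.7 (-0.66, adjusted p = 0.104), Igfbp4 111 and 61.5 (-0.84, adjusted p = 0.132) and Anxa1 429 and 279 (-0.62, adjusted p = 0.134). The collagens Col1a2 and Col1a1 measured 219 and 158 in wild-type and 238 and 160 in null cells. Neuroectoderm markers went the other way. Of 16, none passed over all probe sets (2 higher when adjusted over the list alone), 13 had positive changes and the median was 0.13 (camera adjusted p = 0.0262, or adjusted p = 0.385 with an estimated correlation). The retinoic acid binding genes Crabp1 and Crabp2 had log2 changes of 0.77 and 0.68 (adjusted p = 0.0968 and 0.134). Of 13 trophoblast markers, Igf2 alone fell (1 when adjusted over the list alone), and the median was 0 and the mean -0.09 (camera adjusted p = 0.375). None of 8 Hox genes passed by either count (median 0, camera adjusted p = 0.776).

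By camera, lists of pluripotency genes and of genes of dividing cells lay slightly higher. Of 33 pluripotency genes, Fbxo15 rose (1 when adjusted over the list alone), 20 had positive and 13 negative changes, and the median was 0.12 (camera adjusted p = 0.0188, or adjusted p = 0.212 with an estimated correlation). Tcl1, Dppa3 and Mycn had log2 changes of 0.52, 0.69 and 0.5 (adjusted p = 0.169, 0.187 and 0.215). Nanog, Sox2, Klf4 and Nodal, chosen after their values were seen, were at -0.09, -0.04, -0.23 and -0.31. None of 31 S phase genes or 32 mitosis genes passed alone by either count. Of the S phase genes 26 had positive changes, with a median of 0.11 (camera adjusted p = 0.00152, or adjusted p = 0.196 with an estimated correlation), among them Rrm1 at 0.4 and Mcm7 at 0.29. Of the mitosis genes 28 did, with a median of 0.14 (camera adjusted p = 0.00152, or adjusted p = 0.23 with an estimated correlation), among them Pttg1 at 0.54 and Top2a at 0.29. Chromatin and DNA methylation factors (35 tested, none passing by either count, median 0.06) included the nucleosome-binding Hmgn5 at 0.54 and the methyltransferase Dnmt3a at 0.46 (camera adjusted p = 0.0487, or adjusted p = 0.245 with an estimated correlation). For oxidative phosphorylation (48 tested, none passing by either count) the median was 0.06 (camera adjusted p = 0.0201, or adjusted p = 0.423 with an estimated correlation). Interferon response and MHC class I genes were lower: of 14 none passed over all probe sets (2 lower when adjusted over the list alone), the median was -0.21 (camera adjusted p = 0.0201, or adjusted p = 0.212 with an estimated correlation), and the interferon-induced Gbp2 measured 270 and 149 (-0.85, adjusted p = 0.0745) and the immunoproteasome gene Psmb8 80.8 and 55.4 (-0.53, adjusted p = 0.169).

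**Figure D2:**
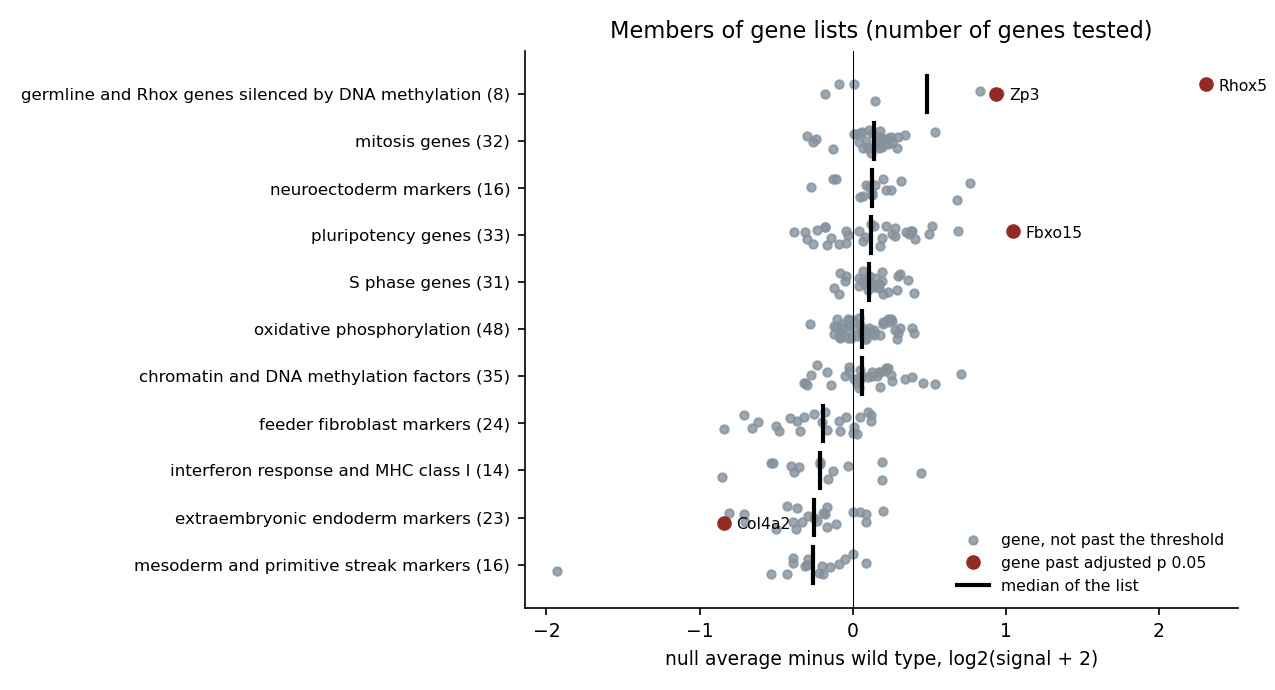
Log2 change (null average minus wild type) of the genes of the lists past camera adjusted p 0.05; each point is a gene, black bars are list medians and red points are genes past adjusted p 0.05. Rhox5, Zp3, Fbxo15 and Col4a2 are the genes past the threshold, and medians run from -0.26 for mesoderm markers to 0.49 for germline and Rhox genes.

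The remaining lists did not pass. Medians were -0.14 for 13 p53 targets (camera adjusted p = 0.0613; Perp at -0.8, the single call when adjusted over the list alone), -0.11 for 18 immediate early genes (0.0613; Ier3 at -0.54), 0.05 for 22 ribosomal protein genes (0.168), 0.06 for 25 genes of the unfolded protein response and amino acid starvation (0.282; Xbp1 at 0.67, the single call when adjusted over the list alone) and -0.05 for 15 cholesterol synthesis genes (0.314). Of 7 core histone genes none passed (median 0.02, camera adjusted p = 0.372; H3c14 at 1.19 ± 0.33, SE, adjusted p = 0.233). Of 25 glycolysis and hypoxia genes none passed by their brightest probe set (2 higher and 2 lower when adjusted over the list alone), and the glucose transporters Slc2a3 and Slc2a1 had log2 changes of -0.63 and -0.49 (adjusted p = 0.132 and 0.19; list median -0.05, camera adjusted p = 0.554). For 15 heat shock genes the median was -0.01, while the mean of 0.01 and the test pointed up (camera adjusted p = 0.797). By limma's fry, 7 lists passed at 0.05: endoderm (adjusted p = 0.0433), fibroblast (0.026), germline and Rhox (0.012), S phase (0.00797), mitosis (0.0433), interferon (0.012) and trophoblast (0.026).

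With an estimated correlation, none of the 11 list calls held, while 5 lists had an unadjusted camera p under 0.05. For the endoderm, germline, S phase, interferon, pluripotency and chromatin lists the estimate lay below the preset 0.01 (between -0.0622 and 0.00861). A higher correlation between genes therefore does not account for the loss of those calls. In the other called lists the estimate lay above 0.01 (between 0.014 and 0.13). The calls for endoderm, fibroblast, S phase and mitosis genes held in every alternative run with the preset correlation. Leaving out arrays ended the call for pluripotency genes (adjusted p = 0.0974 without line 1 replicate 1), interferon genes (0.0543 without line 1 replicate 1 and 0.0514 without wild-type replicate 1), oxidative phosphorylation (0.108 and 0.13 without replicate 1 of line 1 and of line 2, and 0.209 without wild-type replicate 2), neuroectoderm markers (0.0543 and 0.0516 without replicates 1 and 2 of line 1, 0.125 without line 2 replicate 2 and 0.201 without wild-type replicate 1) and chromatin factors (between 0.0514 and 0.191 without each array except line 2 replicate 1).

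Eif2s3y was the only Y-linked gene on the array past the filter. Kdm5d, Uba1y, Uty and Sry, which are Y-linked as well, were measured by 6 probe sets, none of them above background on all 4 null arrays, with null means between 1.95 and 11.9. Uty was above background on 3 null arrays and 0 wild-type arrays, and 1 Sry probe set on 1 null array and both wild-type arrays. Xist, the transcript that coats the inactive X chromosome, was at background on all arrays (7.45 in wild-type and 6.32 in null cells). Genes of the two-cell stage were not tested, since none of the 6 on the array passed the filter.

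Each null line was then compared with wild type separately. Line 1 had 10 calls, 8 higher and 2 lower, with 707 (9.49%) at an unadjusted p under 0.05, and line 2 had 19, 14 higher and 5 lower, with 1051 (14.1%). In both lines Meg3 (by 3.38 in line 1 and 3.5 in line 2), Rhox5 (2.27 and 2.36), Eif2s3y (2.64 and 2.09) and H1f5 (at least 3.63-fold and 2.9-fold) rose, and H1f2 (-2.42 and -2.18) and Igf2 (-1.4 and -1.87) fell. With probe set 93028_at of Mir675 and H19 (2.92 and 2.82), the other Meg3 probe set and the unlisted 95419_at, 9 probe sets passed in both lines, 7 higher and 2 lower. Lists of these sizes would share 0.015 higher and 0.00134 lower probe sets if independent, which leaves out the wild-type arrays that both comparisons use. Simulated unchanged lines, compared with the same simulated wild-type arrays, shared 0 in 100 simulations. They also made 0 calls in the null average, so this count says nothing about sharing. In line 2 alone 10 probe sets passed, and in line 1 alone 1, Prp2, which also differed between the lines. Of the 10, 162020_at differed between the lines in a direct test. Mt4, Cyct, Sgip1, Zp3 and Emp1 did not pass that test (adjusted p between 0.618 and 0.686), nor did Sh3bp1 (0.109) or 101883_s_at (0.387). With limma, the 9 shared calls became 0 and 3 without wild-type replicates 1 and 2, 5 without either replicate of line 1 and 3 without either of line 2. Without wild-type replicate 1, line 1 had 4 calls and line 2 had 0 (643 and 804 at an unadjusted p under 0.05). Without wild-type replicate 2 they had 6 and 4, without either replicate of line 1 6 and 10, and without replicates 1 and 2 of line 2 9 and 9, and 9 and 4. By camera 8 lists passed in line 1 and 9 in line 2, and 0 in either with an estimated correlation, where 2 and 3 had an unadjusted p under 0.05; fry passed 4 and 7.

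The changes of the lines had a covariance of 0.0618 across probe sets, against 0.031 in simulations of unchanged lines (highest 0.0364), a difference of 0.0308. Their correlation was 0.6149 against 0.499 simulated, and 69.7% of the probe sets had the same sign against 66.7%. In the simulations both lines share wild-type arrays that were themselves drawn at the fitted spread, so the excess lies beyond that spread. Part of the excess may still come from a difference that both wild-type arrays carry. The lines were not each compared with a different wild-type array.

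**Figure D3:**
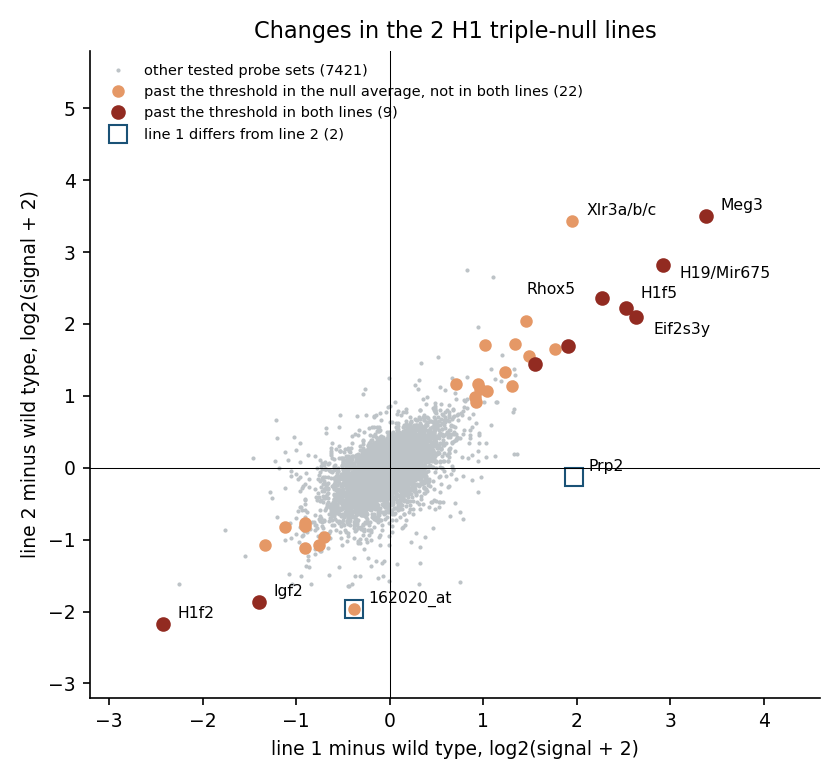
Log2 change of each tested probe set in line 1 (horizontal) and line 2 (vertical) against wild type; dark red points passed the threshold in both lines (9), orange points in the null average and not in both lines (22), and squares mark the 2 that differed between the lines. Meg3, Rhox5, Eif2s3y and H1f5, which was at background in wild-type cells, lie at upper right, H1f2 and Igf2 at lower left, and Prp2 at 1.97 in line 1 and -0.13 in line 2.

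Between the null lines, 2 of 7453 probe sets passed, both higher in line 1, and 563 (7.55%) had an unadjusted p under 0.05; with limma, 0 passed on the side lower in line 1. Prp2, a proline-rich protein gene, measured 117 ± 14.8 in line 1 and 25.6 ± 1.56 in line 2 (SD, n = 2 each), a difference of 2.1 ± 0.14 on the log2 scale (SE, limma adjusted p = 0.0337), with 28.2 in wild-type cells. The unlisted probe set 162020_at measured 33.4 in line 1 and was at background in line 2 (9.75), at least 2.3-fold lower (adjusted p = 0.0418), with 43.8 in wild-type cells. Both fall outside the naming rule, since 162020_at has no gene listed and Prp2 has a brighter probe set (difference 0.27, adjusted p = 0.941), and they were named after their values were seen. Among genes taken by p, none of which passed, Sh3bp1 had a difference of 1.93 (adjusted p = 0.109), and Tcta and the kinase Pim2 had differences of -1.59 and -0.87 (adjusted p = 0.198 and 0.454). Tlx3 and the T cell kinase Zap70 were at background in line 2 and measured 34.2 and 48.7 in line 1, at least 2.36-fold and 3.36-fold higher (adjusted p = 0.112 and 0.168). Meg3 and Rhox5 had differences between the lines of -0.12 ± 0.16 and -0.1 ± 0.18 (SE, limma adjusted p = 0.862 and 0.903). Igf2 and Eif2s3y had larger ones, 0.46 ± 0.14 and 0.55 ± 0.15 (SE, limma adjusted p = 0.627 and 0.618; unadjusted p = 0.0162 and 0.00891). By camera 0 of 23 lists passed, 2 at an unadjusted p under 0.05; the lowest adjusted p was 0.101, for the germline and Rhox list and for trophoblast markers, and 0 passed by fry, 3 at an unadjusted p under 0.05. Leaving out any single array left 0 calls between the lines.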

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

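The tests of explanations in this part were chosen after the result was seen. A difference between the null lines singled out 2 probe sets. Prp2 lay 2.1 higher on the log2 scale in line 1 than in line 2, at 117 against 25.6 intensity units, with 28.2 in wild-type cells. Probe set 162020_at, which has no gene listed, had a fitted difference of 1.59, at 33.4 in line 1 against 9.75 in line 2, where it was at background on both arrays, so that only at least 2.3-fold is measured, with 43.8 in wild-type cells. Among the mouse control probe sets on the array, which were left out of the tests, AFFX-MURINE_b1_at lay 0.43 ± 0.15 (SE) higher in the null average than in wild-type cells, at 2880 ± 338 (SD, n = 4) against 2130 ± 17.5 (SD, n = 2). Its adjusted p over the 19 mouse control probe sets was 0.666.

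Meg3, Igf2, Rhox5 and Eif2s3y changed in the same direction in both null lines. Changes that arose separately in each null culture stay open: 2 probe sets passed between line 1 and line 2 (563 at an unadjusted p under 0.05), against 10 and 19 in comparisons of the same size of each line with wild type (707 and 1051), but the same change can arise more than once, and the 4 genes were chosen because both lines share it. A change of the wild-type culture that the null lines do not share may account for the same picture, since the design holds 1 wild-type line, and it cannot be told apart from the loss of the linker histones, which stays open and untested. Loss of the Y chromosome from the wild-type culture could account for Eif2s3y, but 0 of the 6 other Y-linked probe sets were above background on all null arrays; Uty was above it on 3 null and 0 wild-type arrays and 1 Sry probe set on 1 null and both wild-type arrays, so signals this near to background leave it open.

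A single group of the 4 null arrays against the 2 wild-type arrays gave 35 called probe sets, and the highest count among the other splits of the 6 arrays was 1. Of the 15 splits, 1, the real one, gave as many, and 15 splits are too few for a share under 0.05.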

How the results depend on the processing

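The lists without called genes and the parts of lists were chosen after the data had been seen; the other alternatives were chosen before. H1f2 fell under every alternative that tested it, which the 60th percentile did not (between -2.33 and -2.27 when leaving out arrays). Directions of the called named genes did not turn under any alternative, and median centring changed no count by more than 1.5 times. Quantile normalization and centring moved the median change of all probe sets from -0.01 to 0 and 0.01, and the share of higher calls from 67.7% to 63% and 67.6%. Of the 18 called named genes, the number also called was 15 with no pseudocount, 18 with pseudocount 8, 5 with no filter, 16 after quantile normalization, 18 after centring, 18 with trend, 7 with the replicate block, 13 with the null arrays as a single group, 12 with the 2-fold minimum, and between 5 and 7 when leaving out an array. The filter at the 60th percentile left 10 of them in the test, all called, and gives no value for the rest. Of the 31 calls, 27 were among the 27 made with no pseudocount, 31 among 36 with pseudocount 8, 6 among 8 with no filter, 17 among 64 at the 60th percentile, 30 among 101 with trend and 24 among 35 with the null arrays as a single group.

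With no pseudocount, line 1 had 1 lower call and line 2 had 8 higher and 3 lower. With pseudocount 8, line 2 had 8 lower and the lines differed in 1. With no filter, which adds dim probe sets to the tests, calls were 6 higher and 2 lower in the null average, 4 and 1 in line 1, 3 and 2 in line 2, 3 in both lines and 0 between the lines. At the 60th percentile, which tests fewer probe sets, the null average had 36 lower, line 1 had 7 lower, line 2 had 28 higher and 31 lower, both lines shared 16, and the lines differed in 1, as they did after quantile normalization. With trend, calls were 48 higher and 53 lower in the null average, 22 and 20 in line 1, 47 and 45 in line 2, and 34 in both. A 2-fold minimum left 5 lower. The covariance of the lines' changes was 0.0679 with no pseudocount, 0.0499 with pseudocount 8, 0.086 with no filter and 0.0474 at the 60th percentile. H1f4 had a log2 change of -0.54 with no pseudocount, at signals below background. The cause of these differences was not tested, apart from the number of probe sets tested.

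The labels number the arrays of each line as experiment 1 and 2 without saying whether a number marks a shared day or batch, so pairing by experiment cannot be ruled out. The replicate differences of 2 lines correlated with r of 0.053, 0.095 and 0.073, all too low to take the arrays as paired. After centring on line means, 6 of 6 arrays correlated best with arrays of their own number in other lines. This is a hint from the data, and with 2 arrays per line it says only that every r is above 0. With the number as a block, calls were 12 higher and 2 lower in the null average, all 14 among the 31, 1 lower in line 1 and 0 between the lines, and the Hox list pointed up (adjusted p = 0.967).

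Leaving out an array leaves a line with 1 array, which limma assumes to vary like the others. Counts were then between 6 and 10 higher and between 1 and 4 lower in the null average, 3 to 7 and 1 to 2 in line 1, 0 to 7 and 0 to 4 in line 2, 0 to 5 in both lines and 0 to 0 between the lines. The covariance lay between 0.0607 and 0.1008, lists passing between 6 and 10, H1f3 between -0.11 and 0.11 and H1f4 between -0.3 and 0 (both at background), H2bc22 between -0.22 and 0.02 and Macroh2a1 between -0.18 and 0.03.

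With an estimated correlation 0 lists passed by camera, 5 at an unadjusted p under 0.05, and 7 by fry. The maternally expressed imprinted list pointed down with no filter (adjusted p = 0.416), at the 60th percentile (0.619), without called genes (0.484) and without line 1 replicate 1 (0.651; range over leave-one-out 0.614 to 0.831). Heat shock genes pointed down after quantile normalization (0.996), Hox genes up without 2 of the arrays (range 0.524 to 0.988), and the fibroblast collagens alone up (unadjusted p = 0.776). Without called genes the germline list did not pass (0.18). Chromatin factors did not pass either (0.0536), but none of them was a called gene, so only the adjustment over lists changed for them. Over the alternatives with the preset correlation, adjusted p ran from 0.00137 to 0.18 for the germline list, 0.000487 to 0.0625 for mesoderm, 0.00534 to 0.297 for neuroectoderm, 0.00502 to 0.516 for interferon, 0.00472 to 0.209 for oxidative phosphorylation, 0.019 to 0.191 for chromatin factors and 0.00661 to 0.0974 for pluripotency genes. Among lists that did not pass, it fell as low as 0.00664 for p53 targets, 0.0193 for immediate early genes and 0.0468 for trophoblast markers. Signal over background limits H1f3, H1f4 and the Y-linked genes other than Eif2s3y.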

Other observations

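The tests of explanations in this part, and the parts of lists, were chosen after the result was seen. Probe set 93023_f_at, listed with 12 H3 genes and chosen after its values were seen, measured 121 ± 0.566 (SD, n = 2) in wild-type and 206 ± 12.5 (SD, n = 4) in null cells (log2 0.76, adjusted p = 0.0707). The variant histones H2az1, H2az2 and H2ax measured 1570, 591 and 890 in wild-type and 1630, 603 and 900 in null cells. Other core histone values were 0.12 for the centromeric Cenpa, -0.1 for H2bc22 and -0.07 for Macroh2a1 (adjusted p = 0.718, 0.852 and 0.866). Of the 18 called genes other than H1f2 that lie on a known chromosome, H1f5 and Pfkp lie on the chromosome of H1f2 (11.1% against 3.19% of the genes tested, one-sided Fisher exact p = 0.111). Called probe sets listed with several genes were left out of this count. Among them was the histone probe set 93833_s_at (log2 change -1.2, limma adjusted p = 0.0344). The count covers the whole chromosome, so an effect limited to the neighbourhood of the targeted genes was not tested and stays open.

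Members of lists that did not pass and are not given above went both ways. Among p53 targets, Phlda3, Btg2 and Cdkn1a measured 398, 467 and 158 in wild-type and 311, 378 and 107 in null cells (adjusted p = 0.349, 0.397 and 0.424). The immediate early genes Ccn1 and Dusp1 measured 232 and 607, and 168 and 495 (adjusted p = 0.316 and 0.329). Psat1, a serine synthesis enzyme, had a log2 change of 0.39, the chaperone Pdia3 of -0.57 and Mthfd2, an enzyme of mitochondrial folate metabolism, of 0.26 (adjusted p = 0.261, 0.327 and 0.391). Pdk1, a kinase of pyruvate dehydrogenase, measured 228 and 313 (0.45, adjusted p = 0.214), the ribosomal gene Rpl22 153 and 215 (0.48, adjusted p = 0.229), and the cholesterol gene Sc5d 50.6 and 34.7 (-0.54, adjusted p = 0.33). Hoxb7 and Hoxb6 had log2 changes of -0.33 and -0.28, and the heat shock gene Hspa1a one of -0.26 (adjusted p = 0.478, 0.487 and 0.47).

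Markers of extraembryonic endoderm, mesoderm and fibroblasts were lower in the null lines by camera at the preset correlation (adjusted p = 0.196 for each list with an estimated correlation). Fewer feeder fibroblasts in the null cultures would lower the collagens with the rest. The median change of the 5 collagens was 0.01 (SE 0.05), against -0.32 for the other fibroblast markers. This argues against fewer feeder cells only as far as those cells supply the collagen signal, which was not tested. The collagens had wild-type means between 30.4 (Col6a2) and 219 (Col1a2). The most abundant markers, S100a6 and Tagln, measured 1380 and 1320 in wild-type and 1210 and 1030 in null cells. Of the tested markers, 24 of 24 were above background on both wild-type arrays, with 1 in another list. The 3' to 5' ratio separated wild-type from null arrays for 0 of 2 genes, Gapdh and Actb. This argues only against a difference in RNA quality large enough to separate those ratios, and a smaller one stays open. Fewer differentiated cells of every lineage in the null cultures would lower neuroectoderm markers too, but their median was 0.13 (SE 0.08, with genes taken as independent). With an estimated correlation their rise did not pass (camera adjusted p = 0.385). The median argues against that explanation only as far as differentiated cells supply these signals, which was not tested. The loss of the linker histones, which the design names, stays open and untested.

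The 5 probe sets listed with Sgip1 and Noct together were higher in the null lines, and 3 of them passed the threshold in the null average. A change of the gene Noct itself stays open: its 3 single-gene probe sets had a median log2 change of -0.27 and went both ways, at -0.27 (SE 0.12) for the brightest, -0.48 for the dimmest and 0.63 for 101787_f_at (adjusted p = 0.389). A sequence shared by many loci that the probe sets read together is a candidate explanation: the 5 changes span 0.22, from 0.82 to 1.03. Which loci the probe sets read was not tested, and a rise of Sgip1, whose own probe set rose by 1.37, stays open.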
